A study of Mus musculus with 9 samples.

How the data were processed

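Hindbrains of wild-type C57BL6J mice at 9 stages, E10, E12, E14, E16, E18, P0, P5, P7 and P14, were dissected, dissociated with papain and run on the 10x Chromium 3' version 2 protocol, per the labels. The deposited matrices hold UMI counts per gene and cell barcode that the authors made; per the submitters' processing notes this was done with Cell Ranger 1.2.1 and the mm10 build. The rule that chose the deposited barcodes is not stated. No annotation of cells by the authors was used here, and cell classes were rebuilt. All 9 matrices list the same 27998 Ensembl gene IDs, 56 symbols among them shared by more than 1 ID, and 27722 IDs were found in the GENCODE M21 annotation (GRCm38), from which gene positions were taken. Totals per library ran from 20.6 M UMIs at E18 to 73.9 M at E10, and medians per barcode from 2715 at E18 to 8414.5 at E10. The smallest detectable level, 3 counts of the kept cells, lay between 0.0448 CPM at E10 and 0.158 CPM at E18.

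Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, which removed 690 of 62893. Doublets were scored per library with Scrublet as built into scanpy (30 principal components), and the highest scores were removed at 0.8% per 1000 cells, 3740 barcodes in all and 3.37% to 9.32% per library; Scrublet's own threshold would have marked 0.017% to 7.06%. The 58463 kept cells held 312.59 M UMIs. They were clustered together on 2000 variable genes, leaving out the members of the gene lists that are not cell type markers, with 40 principal components, 20 neighbours and the Leiden method at resolution 1, seed 1, without batch correction. Each of the 37 clusters was named from 28 marker sets fixed in advance. A set could give the name with a mean z score of at least 0.5 and at least 3 markers found in 10% or more of the cells. It also had to have no fewer markers among the cluster's 10 leading genes than any other set. Of such sets the highest score gave the name, even where a set left out scored higher, and a lead under 0.1 left the cluster unnamed. In all, 20 classes were called and cluster 0, mostly at E10 with 8.21% of that library, stayed unnamed. Shares carry exact (Clopper-Pearson) binomial 95% intervals.

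Tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Each library was its stage's only sample, so counts were summed per library, and per library and class, and trends were fitted over stage order from 1 to 9 with edgeR's quasi-likelihood F test (TMM normalization, filterByExpr, Benjamini-Hochberg adjusted p under 0.05, two-sided). Slopes are log2 changes per stage step with their standard errors. A squared term of centred stage order sought mid-course peaks. Trends within classes used the classes with at least 50 cells in at least 6 libraries. Gene lists were tested as the mean over members of log2(CPM + 1) by exact permutation of Spearman's rho and Pearson's r over stage order, over the 30 lists and over 150 pairs of a list and a class. Tumour lists were compared between a class and all other kept cells of the same library, for classes with at least 30 cells in at least 6 libraries and without the class's own markers, by an exact sign-flip permutation test over libraries. All of these tests were two-sided. The stages, markers, lists, tests, thresholds and most alternatives were chosen before the data were examined.

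The 30 lists covered S phase, G2 and M phase, Sonic hedgehog pathway targets, Notch pathway, Wnt pathway, early heterochronic factors, gliogenic factors, Polycomb and DNA methylation enzymes, myelin, synaptic genes, mature and embryonic receptor subunits, cholesterol synthesis, glycolysis, Hox genes, isthmic and cerebellar territory, forebrain, embryonic and adult globins, dissociation and immediate early genes, microglia, endothelial and mesenchymal genes, signatures of WNT, SHH, Group 3 and Group 4 medulloblastoma, and genes altered in SHH medulloblastoma, in Group 3 and 4 medulloblastoma and in pilocytic astrocytoma. Genes named in the results are, among called genes with a mean of at least 20 CPM and without predicted, ribosomal, mitochondrial and globin genes and Xist, the 12 with the steepest slopes each way over all cells, the 5 each way within a class and the 10 with the most negative squared terms. From each list 2 to 4 members with the steepest called slopes, or the highest mean where none was called, and members of the tumour lists were named too. Genes called in all 5 classes were named after their values were seen. Of the genes that these rules select, 1 is not reported here.

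The fits were tested on simulated data with the libraries' own depths and a single common dispersion per comparison, in which 200 genes changed. Differences in dispersion between genes were not simulated, so the rates may not hold for the real genes. For the trend in all cells (15596 genes) 19.2% of genes with a slope of 0.25 and 92% of those with 0.5 were recovered, and 2.63% of the calls were unchanged genes. For the squared term (15991 genes) 24% at 0.1 and 99% at 0.2 were recovered, with 0.806% of calls unchanged. Within classes, slopes of 0.25 and 0.5 were recovered for 62.9% and 100% of genes in the committed precursor-like class (9827 genes, 9.09% of calls unchanged), 54.5% and 98% in granule cell progenitor-like (11731 genes, 4.40%), 49.5% and 97% in granule neuron-like (11119 genes, 3.31%), 33.3% and 99.0% in inhibitory interneuron-like (10337 genes, 4.48%) and 14.7% and 76.5% in oligodendrocyte precursor-like cells (8945 genes, 2.20%). With DESeq2 unchanged genes made up 18.4% of calls in all cells, 14% for the squared term and, in the classes in the same order, 15.5%, 10.3%, 5.33%, 7.25% and 0%. In 200 simulations each, the list test over stage had p under 0.05 in 4% without a trend and in 100% at a slope of 0.25 or 0.5. The sign-flip test did so in 3% without a difference, 91% at 0.5 and 100% at 1 log2 unit. List members were drawn independently of each other, so the recovery rates do not cover lists whose members vary together.

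Alternatives were other size factors (median of ratios), no filter on low counts, DESeq2's Wald test, an exact rank test per gene, limma on means of per-cell CPM, days after conception with birth at day 19 in place of stage order, all barcodes or stricter filters (1000 UMIs, 5% mitochondrial), no doublet removal, resolutions 0.5 and 2, 4000 variable genes, pseudocounts of 0.1 and 10 CPM, TMM library sizes for the lists, list members above 5 CPM, other classes at equal weight, exclusion of erythroid-like, microglia-like, vascular-like and mesenchyme-like cells, each library left out, and the 5 embryonic or 4 postnatal libraries alone. Stages were not compared pairwise for want of replicates, expression was not corrected for free RNA, and splicing, lineage order in pseudotime and human tumour data were not analysed here.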

Results

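Single-cell transcriptomes of the developing mouse hindbrain were measured in 9 droplet libraries that read the 3' ends of transcripts, each from wild-type C57BL6J tissue dissociated with papain. The stages were embryonic days 10, 12, 14, 16 and 18 (E10 to E18) and postnatal days 0, 5, 7 and 14 (P0 to P14), with 1 library per stage and no replicates. Total molecule counts (unique molecular identifiers, UMIs) were 73.9 M (M, the prefix mega) at E10, 36.5 M at E12, 24.4 M at E14, 39.7 M at E16, 20.6 M at E18, 32.4 M at P0, 57.9 M at P5, 36.0087 M at P7 and 26.1 M at P14. After filters, 58463 of 62893 barcodes were kept, from 4074 at P14 to 10566 at P5. Because every stage had a single library, no pair of stages could be compared with a test, and cells were not treated as replicates. Each test below ran over the order of the stages or across libraries. All 5 embryonic libraries shared a row of the index plate and the 4 postnatal libraries came from other rows, so library batch and birth cannot be told apart.

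Which cell classes the hindbrain held at each stage was read from 37 clusters named by marker genes, and class names therefore describe likeness to a type. Early neural progenitor-like cells made up 51.6% (50.5 to 52.8%) of cells at E10 and 2.32% (1.98 to 2.69%) at E12. The intervals here and in the other shares are exact binomial 95% intervals, which cover counting error only, and a count of 0 is given with the limit that 3 cells of the total would make. With finer clusters (resolution 2) these shares were 28.6% and 24.03%, and with 4000 variable genes 51.7% and 24.5%, so the step from E10 to E12 hung on the clustering. From E18 on the class was not seen in the main clusters, with 0 of 5611 cells at E18, which allows a share of up to 0.0535%. Finer clusters gave 0.0356% at E18 and 0.153% at P0, and 4000 variable genes 0.0356% and 0.0873%. Inhibitory interneuron-like cells reached 34.1% (33.0 to 35.2%) at E12. Coarser clusters (resolution 0.5) gave 18.01% and 4000 variable genes 21.9%, and cluster 11 of the class scored 2.74 for serotonergic neurons against 1.43 for its own name. Purkinje cell-like cells, the output neurons of the cerebellar cortex, reached 30.01% (28.82 to 31.21%) at E14. With coarser clusters only 0.0872% of E14 cells kept that name, and the others fell to an inhibitory interneuron-like cluster. Granule cell progenitor-like cells, which proliferate in the outer layer of the young cerebellum, made up 6.31% (5.70 to 6.97%) at E14 and 31.4% (30.3 to 32.6%) at E16 and were most frequent at P5, with 42.6% (41.7 to 43.6%). With granule neuron-like cells they held 7.88% of cells at E14, 46.6% at E16 and 74.7% at P5. Finer clusters gave 26.6% progenitor-like and 8.61% granule neuron-like cells at E16, against 31.4% and 15.1% in the main clusters. There 11.3% of the E16 cells stayed unnamed. At P5 finer clusters gave 42.6% and 32.0%, close to the main 42.6% and 32.1%. Radial glia-like cells made up 14.6% at E16, 0.12% at P5 and 10.6% at P14. The P14 cells lay in a cluster of their own led by Fam107a, Gpr37l1 and Thrsp. That cluster scored 1.93 for radial glia and 1.82 for astrocytes. At P5 cluster 32 held 618 cells and was named astrocyte-like with a score of 1.71 against 1.70 for radial glia. The scores nearly tied, but the name was set by 2 astrocyte markers among the 10 leading genes of that cluster. Every other marker set had 0 there. Across the clusterings tried, the P5 share of radial glia-like cells lay between 0.0759% and 0.283%. Astrocyte-like cells were first counted at P0, at 0.24%, and reached 7.167% (6.394 to 8.003%) at P14. With 4000 variable genes the P14 shares were 0.957% for astrocyte-like and 16.8% for radial glia-like cells, and without doublet removal 0.949% and 17.4%. Oligodendrocyte-like cells were not found before P5 in the main clusters. They made up 0.00946% at P5, 0.761% at P7 and 5.96% (5.26 to 6.74%) at P14. With finer clusters the shares were 0.0873% at P0, 0.634% at P5, 3.52% at P7 and 9.72% at P14.

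**Figure D1:**
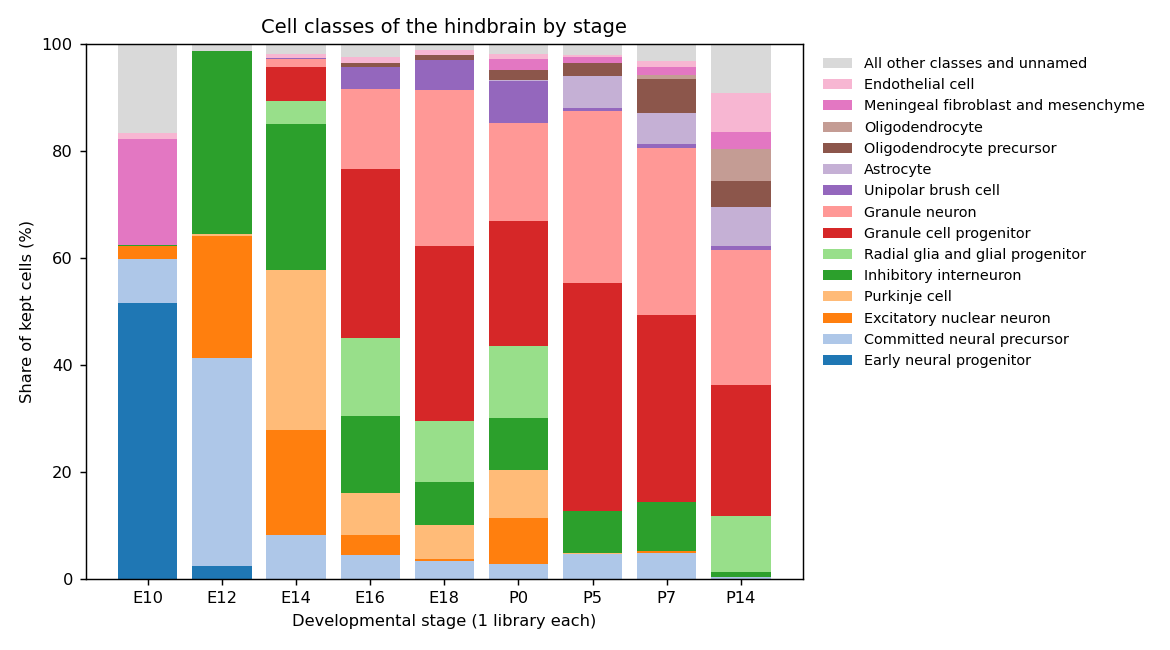
Share of kept cells (y axis, percent) held by each cell class at each stage (x axis, 1 library per stage), with a stacked colour per class. Early neural progenitor-like cells filled 51.6% of the E10 library, and the granule cell progenitor-like class 42.6% of the P5 library.

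The shares of 8 of the 20 called classes followed stage order, 6 upward and 2 downward, after adjustment over the 20 classes. Oligodendrocyte precursor-like cells rose most regularly, from 0 at E10 and E12 through 0.82% at E16 to 6.42% at P7 and 5.03% at P14 (Spearman's rho 0.979, exact permutation p 7.72e-05, adjusted 0.00154; Pearson's r 0.885, exact p 0.000287, adjusted 0.00287; r 0.864 without E10 and P14). With finer clusters the shares of this class were 0.263% at E16, 3.69% at P7 and 1.595% at P14. Ependymal-like cells, the ciliated lining of the ventricles, rose from 0.01% at E16 to 1.37% at P14 (rho 0.966, exact p 0.000198, adjusted 0.00198; r 0.712, 0.940 without E10 and P14). Astrocyte-like (rho 0.895, adjusted exact p 0.0132; r 0.841, 0.80 without E10 and P14) and oligodendrocyte-like cells (0.842 and 0.0132; r 0.605 and 0.619) rose too. So did granule neuron-like (0.845 and 0.0188; r 0.873 and 0.90) and microglia-like cells (0.783 and 0.0431; r 0.798 and 0.852) in the same exact permutation test. Early neural progenitor-like (rho -0.895, adjusted exact p 0.0132; r -0.569, -0.626 without E10 and P14) and floor plate-like cells (-0.842 and 0.0132; r -0.723 and -0.794) fell. All tests were two-sided, and r passed for the same 8 classes and for granule cell progenitor-like cells (r 0.768, adjusted exact p 0.0437, against an adjusted 0.0622 for their rho of 0.733). Committed precursor-like (rho -0.717, adjusted exact p 0.0670) and excitatory nuclear neuron-like cells (-0.736, 0.0622) did not pass. Neither did Purkinje cell-like, inhibitory interneuron-like, unipolar brush cell-like, radial glia-like, choroid plexus-like, endothelial-like, mural-like, mesenchyme-like or erythroid-like cells. When radial glia-like and astrocyte-like cells were counted as 1 class, a grouping chosen after the data were seen, the share had a rho of 0.683 (exact p 0.0503).

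Within the embryonic libraries alone rho was 0.975 for oligodendrocyte precursor-like, 0.975 for granule neuron-like, 0.894 for ependymal-like, -0.90 for early progenitor-like, -0.975 for floor plate-like and -0.30 for microglia-like cells. Within the postnatal libraries alone it was 0.80 for oligodendrocyte precursor-like, 0.80 for astrocyte-like, 0.80 for ependymal-like, 0.20 for granule neuron-like, 1 for oligodendrocyte-like and 1 for microglia-like cells. No class passed within either period after adjustment by the exact permutation test, which with 5 libraries can reach no p under 0.0167 and with 4 libraries none under 0.0833. The unadjusted exact p was under 0.05 for 5 classes over the embryonic libraries. Single libraries decided several calls: the fall of early progenitor-like cells did not pass without E12 (rho -0.846), that of floor plate-like cells without E10, E12 or E14 (-0.764 each), and the rise of astrocyte-like cells without P14 (0.846). The rise of granule neuron-like cells did not pass without E10 or E12 (0.786 each) or without E14 or E16 (0.778 each). That of oligodendrocyte-like cells failed without P5, P7 or P14 (0.764 each), and that of microglia-like cells without E12 (0.786), E14 (0.833), P0, P5, P7 or P14 (0.690 each). Leaving out E12 left 0 falling classes and leaving out E14 left 1, by the same exact test. Other classes passed only in a part of the data. Granule cell progenitor-like cells passed without P14 (rho 0.905), and committed precursor-like cells without P5 or P7 (-0.833 each) or without doublet removal (-0.767). Excitatory nuclear neuron-like cells passed without E10 (-0.886) or P0 (-0.814), inhibitory interneuron-like cells without E10 (-0.881) and mesenchyme-like cells without E10 (0.903).

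How the whole tissue's expression moved with stage was tested on counts summed over each library. The 12 steepest risers included genes of myelin and of astrocytes. Mog (ENSMUSG00000076439, chromosome 17, 37010743 to 37023398), which encodes a glycoprotein on the outer face of myelin, had 0 counts per M UMIs (CPM) from E10 to P0, 2.01 CPM at P5, 98.2 CPM at P7 and 762 CPM at P14. Mobp (ENSMUSG00000032517, chromosome 9, 120149707 to 120181484), a gene of compact myelin, stood at 0.134 CPM at E10, 477 CPM at P7 and 1805 CPM at P14. Mag (ENSMUSG00000036634, chromosome 7, 30899176 to 30914873), whose product binds the axon surface, rose from 0.433 to 1259 CPM between E10 and P14, a slope of 1.47 on the log2 scale per stage step (SE 0.21, 9 libraries, adjusted p 0.00297). Among astrocyte genes, Aqp4 (ENSMUSG00000024411, chromosome 18, 15389496 to 15410982), the water channel of astrocyte endfeet, rose by 1.49 per step (SE 0.15, adjusted p 0.000811), from 0.448 to 734 CPM. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the glial filament gene, reached 14.2 CPM at P0 and 204 CPM at P7. Gpr37l1 (ENSMUSG00000026424), a receptor of astrocytes, reached 619 CPM at P14. Ptgds (ENSMUSG00000015090), a prostaglandin synthase of meninges and glia, rose from 0.134 to 1123 CPM (slope 1.58, SE 0.12). Pllp (ENSMUSG00000031775), a membrane protein of myelinating cells, rose from 0.179 to 316 CPM (slope 1.48, SE 0.12). The others of the 12 steepest risers were Agt (ENSMUSG00000031980), Ermn (ENSMUSG00000026830), Cldn11 (ENSMUSG00000037625) and Mndal (ENSMUSG00000090272), an interferon-inducible gene that stood at 0.105 CPM at E10 and 134 CPM at P7. The slope of Cldn11 was 1.22 (SE 0.25) over all libraries and -0.24 over the embryonic libraries alone.

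The 12 genes that fell most steeply included several known from early patterning and progenitors. Hmga2 (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469), a chromatin protein of early progenitors, fell from 370 CPM at E10 to 0.168 CPM at P14, a slope of -1.13 per step (SE 0.13, 9 libraries, adjusted p 0.00106). Igf2bp1 (ENSMUSG00000013415, chromosome 11, 95957163 to 96005940), an RNA-binding protein of fetal tissue, fell from 252 to 0.546 CPM (slope -0.99, SE 0.12, adjusted p 0.00135). Msx3 (ENSMUSG00000025469, chromosome 7, 140046157 to 140049089), a homeobox gene of the dorsal neural tube, fell from 146 to 0.252 CPM (slope -1.27, SE 0.11, adjusted p 0.000426). Crabp1 (ENSMUSG00000032291, chromosome 9, 54764748 to 54773110), which encodes a retinoic acid-binding protein, fell from 1138 to 1.55 CPM (slope -1.04, SE 0.21), and Crabp2 (ENSMUSG00000004885), its relative, from 623 to 7.39 CPM (slope -0.85, SE 0.17). Otp (ENSMUSG00000021685), a homeobox gene of neurons, was highest at E12, with 183 CPM, and had no UMI at P14. Mn1 (ENSMUSG00000070576), Meis2 (ENSMUSG00000027210), Ebf2 (ENSMUSG00000022053), Olig3 (ENSMUSG00000045591) and Pxylp1 (ENSMUSG00000043587) also peaked at E12, at 540, 566, 229, 136 and 127 CPM, and ended at 6.003, 2.23, 3.99, 1.09 and 2.52 CPM. Fgf15 (ENSMUSG00000031073), a growth factor of the embryonic brain, had 112 CPM at E14 and 0.042 CPM at P14. Over the postnatal libraries alone the slopes of Crabp1, Crabp2 and Olig3 were 0.05, 0.31 and 0.10. The fall of Fgf15 (slope -1.04, SE 0.30, adjusted p 0.0408) did not pass without E12 (-1.20), E14 (-1.03), E16 (-1.03), P5 (-0.94), P7 (-0.89) or P14 (-0.78). That of Meis2 did not pass without E12 (-0.82) or P14 (-0.83), and that of Mn1 without P14 (-0.75).

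Of 15774 genes tested with edgeR's quasi-likelihood F test, 1605 rose and 1192 fell with stage order at an adjusted p under 0.05, together 17.7% of the genes. At the unadjusted level 2705 rising and 2642 falling genes had a p under 0.05. The scatter around the trend corresponded to a biological coefficient of variation of 47.0%. With the embryonic libraries alone 1 gene rose and 1 fell (1395 and 1663 at an unadjusted p under 0.05). With the postnatal libraries alone 16 rose and 1 fell (1674 and 849 unadjusted). Of the called genes that could be tested there, 95.5% of 2559 had the same sign in the embryonic and 94.3% of 2668 in the postnatal libraries. The calls were made on these same libraries, so the shares are not independent evidence. A fit with a term for embryonic against postnatal libraries, added after the data were seen, called 5 rising genes and 1 falling gene, with 1296 and 1618 at an unadjusted p under 0.05. The counts moved with single libraries: 2465 rose and 1964 fell without E10, 1056 and 597 without E12, 629 and 492 without P14, and 779 fell without P5. DESeq2 called 2023 falling genes, and an exact permutation test of Spearman's rho per gene called 589. The fall of Crabp1 did not pass without E10 and P14 together (slope -0.77) or on means of per-cell CPM (-0.80), nor the rise of Ermn on those means (0.56).

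Genes that peaked in mid-course were sought with a squared term of stage order. The Purkinje cell genes Pcp2 (ENSMUSG00000004630, chromosome 8, 3623371 to 3625545), Calb1 (ENSMUSG00000028222, chromosome 4, 15881264 to 15908064), a calcium buffer, Car8 (ENSMUSG00000041261) and Pcp4 (ENSMUSG00000090223) were highest at P0, at 314, 456, 375 and 1631 CPM. Their squared coefficients were -0.50 (SE 0.08), -0.39 (SE 0.05), -0.35 (SE 0.08) and -0.35 (SE 0.06), with adjusted p values of 0.0143, 0.0119, 0.0429 and 0.0158. Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), a transcription factor of unipolar brush cells, peaked at E18 with 101 CPM (coefficient -0.42, SE 0.06, adjusted p 0.0141). Hpca (ENSMUSG00000028785), a neuronal calcium sensor, peaked at E18 with 71.2 CPM, and Islr2 (ENSMUSG00000051243) and the neuropeptide gene Sst (ENSMUSG00000004366) at P0 with 272 and 175 CPM. Fgf15 (ENSMUSG00000031073) was highest at E14 with 112 CPM, and the phosphatase subunit gene Ppp2r2c (ENSMUSG00000029120) at P5 with 519 CPM. Pcp2, Calb1, Car8, Pcp4 and Eomes were also markers of Purkinje cell-like and unipolar brush cell-like classes, whose shares were highest between E14 and P0. Purkinje cell-like cells made up 9.06% at P0 but 0.237% at P5, 0.0895% at P7 and 0 at P14. Unipolar brush cell-like cells made up 7.70% at P0 and 0.568% at P5. Peaks of these genes in all cells thus cannot be told apart from changes in the shares of captured cells. In all, 365 genes had a positive and 475 a negative squared term among 16262 tested (edgeR, unadjusted counts 1808 and 2136). Without E10, 79 genes were positive and 111 negative, without E16 110 and 133, and without E18 39 and 43. The counts were 224 and 229 without P0, 185 and 232 without P7, and 55 and 182 without P14. DESeq2 called 1077 and 1467. The call for Pcp2 did not pass without E18 (coefficient -0.50), those for Pcp4 and Eomes without E10 (-0.29 and -0.40) or E18 (-0.35 and -0.41). That for Islr2 did not pass without E10 (-0.25) or P14 (-0.32). With 1 library left out, Car8 passed only without E10 or E12, and had -0.36 without E14, E16 or P14, -0.35 without E18, P5 or P7 and -0.30 without P0. Sst did not pass without E10 (-0.33), E16 (-0.32), E18 (-0.32), P0 (-0.24), P7 (-0.32) or P14 (-0.30).

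Gene lists fixed in advance were followed over stage as the mean log2(CPM + 1) of their members, with exact two-sided permutation tests adjusted over 30 lists. Gliogenic factors, the nuclear factor I genes and their partners in the switch to glia, rose almost without a break (rho 0.983, exact p 4.96e-05, adjusted 0.000744; r 0.896, exact p 3.31e-05, adjusted 0.000579; 0.939 without E10 and P14). Its rho was 1 in the embryonic and in the postnatal libraries. Of 6 genes tested, 4 rose over all genes tested and 5 adjusted over the list alone, led by Nfix (slope 0.84, SE 0.24; 0.179 CPM at E10, 656 CPM at P5), Nfib (slope 0.53, SE 0.16) and Sox8 (slope 0.35, SE 0.07). Myelin genes rose (rho 0.867, adjusted exact p 0.0271; r 0.835, adjusted 0.00198; 0.820 without E10 and P14; rho 0.20 embryonic and 1 postnatal) and all 10 passed, also when adjusted over the list alone. Microglia genes rose (rho 0.950, adjusted exact p 0.00265; r 0.922, adjusted 0.00255; 0.871 without E10 and P14; rho 0.70 embryonic and 1 postnatal), with 7 of 7 passing in both counts. The complement gene C1qa went from 2.21 to 137 CPM (slope 0.68, SE 0.07) and Tyrobp had a slope of 0.55 (SE 0.10). Early heterochronic factors, RNA-binding and chromatin proteins of the fetal program, fell (rho -0.950, adjusted exact p 0.00265; r -0.932, adjusted 0.000579; -0.932 without E10 and P14; rho -0.70 embryonic and -1 postnatal). All 7 tested members fell in both counts, among them Lin28b (22.3 to 0.042 CPM, slope -0.92, SE 0.11), Trim71 (slope -1.23, SE 0.16) and Hmga2. Isthmic and cerebellar territory genes fell (rho -0.983, adjusted exact p 0.000744; r -0.959, adjusted 0.00149; -0.964 without E10 and P14; rho -0.90 embryonic and -1 postnatal). In this list 4 of 8 fell over all genes tested and 5 adjusted over the list alone, led by the growth factor Fgf17 (53.4 CPM at E12; slope -1.86, SE 0.22), Pax8 and Pax5 (35.8 CPM at E12; slope -1.05, SE 0.11).

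Notch pathway genes fell as well (rho -0.850, adjusted exact p 0.0304; r -0.874, adjusted 0.00935; -0.794 without E10 and P14; rho -0.70 embryonic and -0.40 postnatal), 6 of 12 in both counts. The ligand gene Dll1 fell from 94.0 CPM at E12 to 1.68 CPM at P14 (slope -0.63, SE 0.09), the effector gene Hes5 from 855 to 25.3 CPM (slope -0.55, SE 0.06) and Nrarp from 203 CPM at E10 to 13.0 CPM (slope -0.49, SE 0.07). Over the embryonic libraries alone, and over the postnatal ones alone, 0 lists passed by the exact permutation test. An unadjusted exact p under 0.05 over the embryonic libraries was reached by 5 lists: gliogenic factors, embryonic globins, Group 4 medulloblastoma signature genes, and the altered genes of Group 3 and 4 medulloblastoma and of pilocytic astrocytoma. The Notch call did not pass without E10 or E12 (rho -0.786 each), E16, E18 or P0 (-0.857 each) or P7 or P14 (-0.833 each). The myelin call did not pass without E16 (0.857) or without P0, P5, P7 or P14 (0.810 each). Nor did it pass with a pseudocount of 0.1 CPM (0.817) or 10 CPM (0.80), with TMM library sizes (0.817), or without the erythroid-like, microglia-like, vascular-like and mesenchyme-like cells (0.80).

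**Figure D2:**
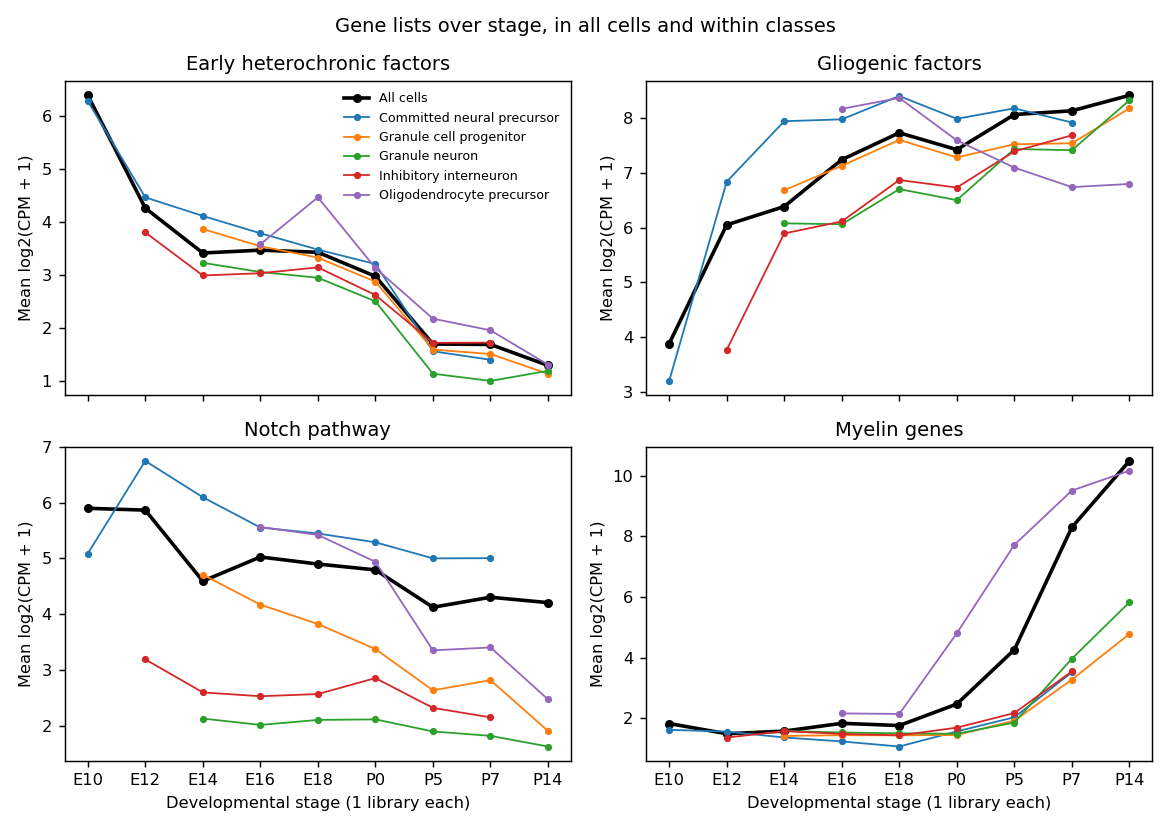
Mean log2(CPM + 1) of 4 gene lists (y axis) against stage (x axis, 1 library each), in all cells (black) and in the 5 classes with enough cells (colours). Early heterochronic factors ended lower than they began in all 5 classes, and in granule cell progenitor-like cells went from 3.87 to 1.14.

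The remaining lists did not pass over stage by rho, each with its adjusted exact permutation p. Wnt pathway genes had a rho of -0.75 (0.0765), with 4 falling members over all genes tested and 4 adjusted over the list alone. Wnt3a and Wnt1 went from 12.6 and 18.0 CPM at E10 to 0 at P14, Rspo1 from 47.3 to 0.168 CPM, and Axin2 had a slope of -0.17 (SE 0.05). S phase genes (rho -0.183, 0.690) and G2 and M phase genes (rho -0.0833, 0.872) had 0 of 20 members each passing with edgeR, over all genes tested or adjusted over the list alone. Their means were highest at E10 (7.27 and 7.75), lowest at E14 (4.71 and 4.90) and again high at P5 (6.56 and 7.47). Glycolysis genes (rho -0.583, 0.191) held 4 falling members and 6 adjusted over the list alone, among them Pfkl (slope -0.26, SE 0.05) and Pkm (2514 CPM at E10, 499 CPM at P14). Cholesterol synthesis genes (rho -0.05, 0.912; 0 of 14 in both counts) were led by Hmgcs1, with a mean of 345 CPM. Synaptic genes (rho 0.25, 0.625) had 2 rising members of 16 over all genes tested, Slc17a7 (0.134 to 13.4 CPM) and Sv2b. Mature receptor subunits (rho 0.567, 0.201) had Gabrd rising to 7.56 CPM. Embryonic receptor subunits (rho 0.667, adjusted exact p 0.147; r 0.763, adjusted 0.0120) had Slc12a2, the chloride importer gene, rising to 99.6 CPM (slope 0.32, SE 0.06) and 2 members adjusted over the list alone. Polycomb and DNA methylation enzymes (rho -0.483, 0.291) had Tet1 rising (slope 0.12, SE 0.03) and Eed falling (slope -0.18, SE 0.05), and 0 members adjusted over the list alone.

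Lists that follow tissue pieces and handling gave these values, by the same exact permutation test with adjusted p values. Dissociation and immediate early genes had a rho of 0.70 (0.118), with 3 of 15 members rising over all genes tested and 7 adjusted over the list alone: Ier3 (slope 0.42, SE 0.05), Junb (slope 0.41, SE 0.10) and Fosb (slope 0.40, SE 0.12). Endothelial genes had a rho of 0.75 (0.0765), with 2 rising members and 3 adjusted over the list alone. Cldn5 stood at 0.242 CPM at E12 and 1061 CPM at P14. Mesenchymal genes (rho 0.633, 0.163) had Dcn rising (slope 1.03, SE 0.26). Embryonic globins (rho -0.75, 0.0765; r -0.692, adjusted exact p 0.00893; 3 of 3 falling) stood at 4809.9 CPM for Hbb-y at E10. Adult globins (rho 0.483, 0.291; 0 passing in both counts by edgeR) stood at 11480.0 CPM for Hbb-bs at P14 and 3.02 CPM at E12. Hox genes (rho -0.633, 0.163), which mark hindbrain behind the cerebellum and spinal cord, had 4 of 16 members tested, 2 falling over all genes tested and 4 adjusted over the list alone. Hoxa2 stood at 82.5 CPM at E10 and 0.21 CPM at P14. The mean of the Hox list went up and down between neighbouring stages. It was 0.586 at E16, 0.0179 at E18, 0.572 at P0, 0.0261 at P5, 0.338 at P7 and 0.032 at P14. Whether the dissected region differed between libraries was not tested. Such a difference would bear on class shares and on trends in all cells. Forebrain genes (rho -0.75, 0.0765; r -0.799, adjusted exact p 0.0314) had 3 members tested, with Dlx2 falling (slope -0.81, SE 0.14) and 2 adjusted over the list alone. Without E10 the rho of mesenchymal genes passed at 0.976, without P14 that of embryonic globins at -1, and without P5 those of dissociation and endothelial genes at 0.881 each. Endothelial genes (0.817) and embryonic receptor subunits (0.833) passed with a pseudocount of 10 CPM, mesenchymal genes with members above 5 CPM (0.817), and forebrain genes by r on days (-0.813). Embryonic globins (-0.983) and Wnt pathway genes (-0.867) passed without the erythroid-like, microglia-like, vascular-like and mesenchyme-like cells.

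Within classes, counts were summed over the cells of a class in each library, from 0.158 to 24.0 M UMIs. This set change with stage apart from the mix of classes, but not from a change of clusters within a class. Granule cell progenitor-like cells, in 7 libraries from E14 to P14, gained Sfrp1 (ENSMUSG00000031548), a secreted Wnt modulator (14.8 CPM at E14, 617 CPM at P5, 206 CPM at P14; slope 0.82, SE 0.18). They also gained Mndal (ENSMUSG00000090272) (17.3 to 249 CPM; slope 0.86, SE 0.10) and Myod1 (ENSMUSG00000009471), a gene known from muscle (0.641 to 100.2 CPM; slope 1.15, SE 0.11). The myelin gene Mbp (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637) (5.77 to 748 CPM; slope 1.21, SE 0.12) rose in the same cells. Falling genes were led by Mn1 (ENSMUSG00000070576), a transcriptional coregulator (514 CPM at E14, no UMI at P14), and Thsd7b (ENSMUSG00000042581) (89.8 to 0.223 CPM; slope -1.60, SE 0.17). Others were Pxylp1 (ENSMUSG00000043587), Pde2a (ENSMUSG00000030653) and Igfbp2 (ENSMUSG00000039323), a binding protein of insulin-like growth factors (549 to 0.668 CPM; slope -1.45, SE 0.25). In all, 1015 genes rose and 1066 fell of 11865 tested (edgeR), and 611 of these were called in the same direction in all cells. The class lay mostly in clusters 18 and 20 up to P0 and in clusters 16, 25 and 27 from P5 on. Without E16, 595 rose and 602 fell, and 652 rose without E14 and 652 without P7. Sfrp1 did not pass without E14 (slope 0.70) or E16 (0.86).

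Granule neuron-like cells, in 7 libraries from E14 to P14, gained Mndal (ENSMUSG00000090272) (5.31 to 280.2 CPM; slope 1.74, SE 0.26) and the related Ifi203 (ENSMUSG00000039997) (no UMI at E14, 148 CPM at P14). Tgfb2 (ENSMUSG00000039239), a growth factor gene, stood at 5.31 CPM at E14 and 166 CPM at P7 (slope 1.28, SE 0.23). Mbp (13.3 to 1830.4 CPM; slope 1.35, SE 0.17) rose in this class too. Pde2a (ENSMUSG00000030653), a phosphodiesterase gene, fell from 186 to 0.56 CPM (slope -1.65, SE 0.13), and Epha5 (ENSMUSG00000029245), an axon guidance receptor, from 544 to 6.72 CPM (slope -1.26, SE 0.17). Mn1, Cbln2 (ENSMUSG00000024647) and Cdh11 (ENSMUSG00000031673) fell with them. Of 11294 genes tested, 546 rose and 568 fell (edgeR), 417 of them as in all cells. Cells of the class lay mostly in cluster 19 up to P0 and in clusters 29 and 30 from P5 on. Without E16, 295 rose and 262 fell, and 345 fell without P7. Mn1 did not pass without P7 (slope -1.40) or P14 (-1.53).

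Committed precursor-like cells, in 8 libraries from E10 to P7, gained Tfap2c (ENSMUSG00000028640) (2.06 to 128 CPM; slope 1.12, SE 0.11), Dbx2 (ENSMUSG00000045608), a homeobox gene (1.55 to 266 CPM; slope 1.08, SE 0.11), St8sia5 (ENSMUSG00000025425), Mndal and Ptgds. They lost Nkx6-1 (ENSMUSG00000035187), a homeobox gene of the ventral neural tube (193 CPM at E10, no UMI at P7), Crabp2 (764 to 1.201 CPM; slope -2.04, SE 0.15), Otp (239 CPM at E10, no UMI from E16 on), Olig3 and Hoxa2 (ENSMUSG00000014704). Of 10057 genes tested, 833 rose and 879 fell (edgeR), 497 as in all cells. Without P5, 393 rose and 460 fell, and 554 fell without P7. With finer clusters 363 rose and 436 fell. Ptgds did not pass without P7 (slope 0.64). The class lay mostly in clusters 3 and 10 up to E14 and in cluster 22 from E16 on. At E10 cluster 3 held 593 of its cells, and that cluster scored 2.08 for cranial motor and visceral neurons against 1.57 for its own name. With finer clusters the share of the class at E10 was 0.895% instead of 8.21%, so losses counted from E10 can come in part from a change of cells.

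Inhibitory interneuron-like cells, in 7 libraries from E12 to P7, gained Klf9 (ENSMUSG00000033863), a transcription factor gene (0.696 to 77.7 CPM; slope 1.26, SE 0.17), and Kcna2 (ENSMUSG00000040724), a potassium channel gene (2.78 to 146 CPM; slope 1.06, SE 0.10). Further risers there were Nfix (ENSMUSG00000001911) (1.29 to 1809 CPM; slope 1.08, SE 0.25), Tuba4a (ENSMUSG00000026202) and Tmem114 (ENSMUSG00000022715). They lost Olig3 (236 CPM at E12, no UMI at P5 or P7), Mab21l2 (ENSMUSG00000057777) (139 to 0.514 CPM; slope -1.53, SE 0.16) and Robo3 (ENSMUSG00000032128), a guidance receptor gene (194 to 1.03 CPM; slope -1.26, SE 0.08). Dlk1 (ENSMUSG00000040856) and Dmrtb1 (ENSMUSG00000028610) fell as well. Of 10551 genes tested, 466 rose and 459 fell (edgeR), 322 as in all cells. Without E14 the counts were 137 and 156, without P5 146 and 167 and without P7 240 and 287. DESeq2 called 800 and 828. Nfix did not pass without E14 (slope 1.30), P5 (1.04) or P7 (1.24). Tuba4a and Tmem114 did not pass without E14 (1.05 and 0.95) or P5 (1.13 and 1.06). Cells of the class lay mostly in clusters 11 and 13 at E12 and E14 and in cluster 23 later. At E12 clusters 11 and 13 held 1222 and 1191 cells and cluster 23 held 0. At P5 cluster 23 held 822 and the others 0. Robo3 and Olig3 were among the leading genes of cluster 13. Losses counted from E12 can thus come in part from a change of cells.

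Oligodendrocyte precursor-like cells, in 6 libraries from E16 to P14 gained Mbp (7.59 to 18879 CPM; slope 2.22, SE 0.23). Mobp (no UMI up to P0, 1919 CPM at P14), Cldn11 (slope 2.18, SE 0.15) and Cryab (ENSMUSG00000032060), a small heat shock gene, also rose. The class lost Cyp26b1 (ENSMUSG00000063415), an enzyme that degrades retinoic acid (98.6 to 1.28 CPM; slope -1.60, SE 0.19) and Grb10 (ENSMUSG00000020176), an imprinted adaptor gene (209 to 1.28 CPM; slope -1.36, SE 0.10), along with Kitl (ENSMUSG00000019966), Wnt5a (ENSMUSG00000021994) and Mmp14 (ENSMUSG00000000957). The class was a single cluster that scored 2.32 for oligodendrocytes against 2.59 for its own name, and finer clusters set apart an oligodendrocyte-like cluster of 392 cells with Enpp6 and Mbp among its leading genes. In the 563 cells then left, with P0 to P14 only, 17 genes rose and 3 fell. There the slope of Mbp was 1.25, and Cldn11 (0.26) and Grb10 (-1.07) did not pass. Clusters and libraries changed together there, so the lower counts cannot be put down to either. Of 9311 genes tested, 1014 rose and 612 fell (edgeR), 425 as in all cells. Without P14 the counts were 468 and 293, and without P7 605 and 362. In all 5 classes at once, 9 of 8335 genes tested in each rose, and 17 fell. The rising ones, named after their values were seen, included the iron carrier gene Trf (mean slope 0.88), Klf9 (0.78), Cd9 and the glutamate receptor gene Gria4. The falling ones included Mn1 (mean slope -1.24), Igf2bp1 (-1.21), Igf2bp2 (-0.98), Epha5 (-0.95), Grb10, Nr2f2 and Hes6.

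The lists were also followed within the 5 classes, giving 150 pairs of a list and a class, of which 4 rose and 6 fell by the exact permutation test after adjustment over the pairs. Early heterochronic factors fell at every step in committed precursor-like cells (rho -1, exact p 4.96e-05, adjusted 0.00739; r -0.957, -0.919 without the end libraries), from 6.29 to 1.40 on the log2 scale. They did so too in granule cell progenitor-like cells (rho -1, adjusted exact p 0.0118; r -0.970, -0.955), from 3.87 to 1.14. In each of these classes 5 of 5 tested members fell over all genes tested and adjusted over the list alone. Notch pathway genes fell in granule cell progenitor-like cells (rho -0.964, adjusted exact p 0.0414; r -0.980, -0.947), where 5 of 9 members fell in both counts. Hes5 went from 367 to 1.34 CPM (slope -1.25, SE 0.10) and Hes1 from 135 to 0.223 CPM. Cholesterol synthesis genes fell in inhibitory interneuron-like cells (rho -1, adjusted exact p 0.0118; r -0.972, -0.976). There 9 of 12 fell over all genes tested and 10 adjusted over the list alone, among them Hmgcs1 (673 to 60.7 CPM; slope -0.61, SE 0.04) and Fdft1 (326 to 34.0 CPM). In the same class dissociation and immediate early genes had a rho of 0.929 (adjusted exact p 0.0628; r 0.928), with 6 of 13 members rising and 8 adjusted over the list alone. The list did not pass in the other classes either, but 5 of 14 members rose in granule neuron-like cells (r 0.805), 3 of 14 in granule cell progenitor-like and 3 of 12 in committed precursor-like cells, while 5 of 13 fell in oligodendrocyte precursor-like cells. Handling may thus have differed with stage, which bears on all trends within classes. Glycolysis genes fell in granule neuron-like cells (rho -1, adjusted exact p 0.0118; r -0.960, -0.939), 4 of 8 and 7 adjusted over the list alone, with Pfkl at a slope of -0.40 and Ldha at -0.30. Forebrain genes fell in granule neuron-like cells (rho -1, adjusted exact p 0.0118; r -0.985, -0.964), both of the 2 tested members in either count, Neurod6 from 382 to 75.9 CPM and Dlx2.

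Gliogenic factors rose in inhibitory interneuron-like cells (rho 0.964, adjusted exact p 0.0414; r 0.909, 0.948 without the end libraries; 2 of 5 members, Nfix and Zbtb20, and 4 adjusted over the list alone). Myelin genes rose in granule cell progenitor-like cells (rho 0.964, adjusted exact p 0.0414; r 0.842, 0.827; 3 of 5 in both counts, Mbp and Cldn11 among them). In the same cells 3 of 4 adult globin genes rose (list rho 0.607, adjusted exact p 0.276), as did 2 of 3 microglia genes tested (rho 0.893, adjusted exact p 0.0690), and these too are genes of other cell types. Embryonic receptor subunits rose in granule neuron-like cells (rho 0.964, adjusted exact p 0.0414; r 0.865, 0.965 without the end libraries), with Slc12a2 passing (slope 0.36, SE 0.07) and 2 adjusted over the list alone. Endothelial genes had a rising mean in granule neuron-like cells (rho 0.964, adjusted exact p 0.0414; r 0.789, 0.908), with 0 of 3 members passing by edgeR in either count and Cldn5 ending at 5.60 CPM. Hmga2, Lin28b, Hes5 and the myelin genes also served as markers of other classes. None of the 10 pairs passed when E14, E16, P0, P5 or P7 was left out, with 6 or 7 libraries in the test, though each rho stayed at or beyond 0.943 in size. Without E12 the gliogenic pair did not pass (0.943), without E18 neither did the Notch (-0.943) and endothelial pairs (0.943), and without P14 the Notch (-0.943), myelin, receptor and endothelial pairs (0.943 each) did not. With a pseudocount of 10 CPM 9 pairs rose and 14 fell, but the myelin pair did not pass (0.75). With finer clusters 2 pairs rose, and the receptor (0.943), endothelial (0.771) and forebrain pairs (-0.943) did not pass. Whether a list moved differently between classes was tested for 240 pairs of classes and lists, and the smallest adjusted exact p was 0.0511.

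Which classes of normal cells express genes that mark or are altered in childhood cerebellar tumours was asked for 8 lists in 8 classes. Each class was set against all other cells of the same library, with an exact two-sided sign-flip permutation test over libraries adjusted over 64 pairs. The Sonic hedgehog list holds genes switched on by the mitogen of granule cell progenitors, and also pathway components such as Gli2 and Boc. This list of Sonic hedgehog pathway targets was higher in granule cell progenitor-like cells by 1.22 on the log2 scale (SD 0.23, higher in 7 of 7 libraries, exact p 0.0156, adjusted 0.0312). In those cells Gli2, a transcription factor of the pathway, stood at 31.1 CPM ± 11.0 (SD, n = 7) against 4.95 CPM in the other cells, and Ccnd2, a cyclin gene, at 1775 CPM ± 515 against 479.9 CPM. Boc, a coreceptor gene, stood at 46.6 CPM ± 10.3 against 12.8 CPM, and Mycn at 226 CPM ± 61.4 against 82.3 CPM. Genes altered in SHH medulloblastoma were higher in the same class by 0.46 (SD 0.10, 7 of 7 libraries, adjusted exact p 0.0312), where Smo, the pathway's transducer, stood at 40.6 CPM ± 5.25 against 17.2 CPM. They were also higher in committed precursor-like cells, by 0.27 (SD 0.21, 8 of 8 libraries, exact p 0.00781, adjusted 0.0312), where Tcf4 stood at 1187 CPM ± 593 against 549 CPM. This call did not pass with finer clusters (0.21). Group 4 medulloblastoma signature genes, without the class marker Eomes, were higher in unipolar brush cell-like cells by 1.84 (SD 0.96, 6 of 6 libraries, exact p 0.0312, adjusted 0.0400). With 6 libraries this is the smallest p the exact test can give. There Khdrbs2, an RNA-binding protein gene, stood at 243 CPM ± 95.02 (SD, n = 6) and Unc5d, a guidance receptor gene, at 72.4 CPM ± 27.0, against 45.2 and 7.59 CPM in the other cells. As single genes each had an adjusted exact p of 0.0545. Genes altered in Group 3 and 4 medulloblastoma, without the class marker Otx2, were lower in the same class by -0.46 (SD 0.28, 0 of 6 libraries higher, adjusted exact sign-flip p 0.0400). Group 3 signature genes did not pass there (0.23, adjusted exact sign-flip p 0.400). Leaving out any library with this class left too few for its test.

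**Figure D3:**
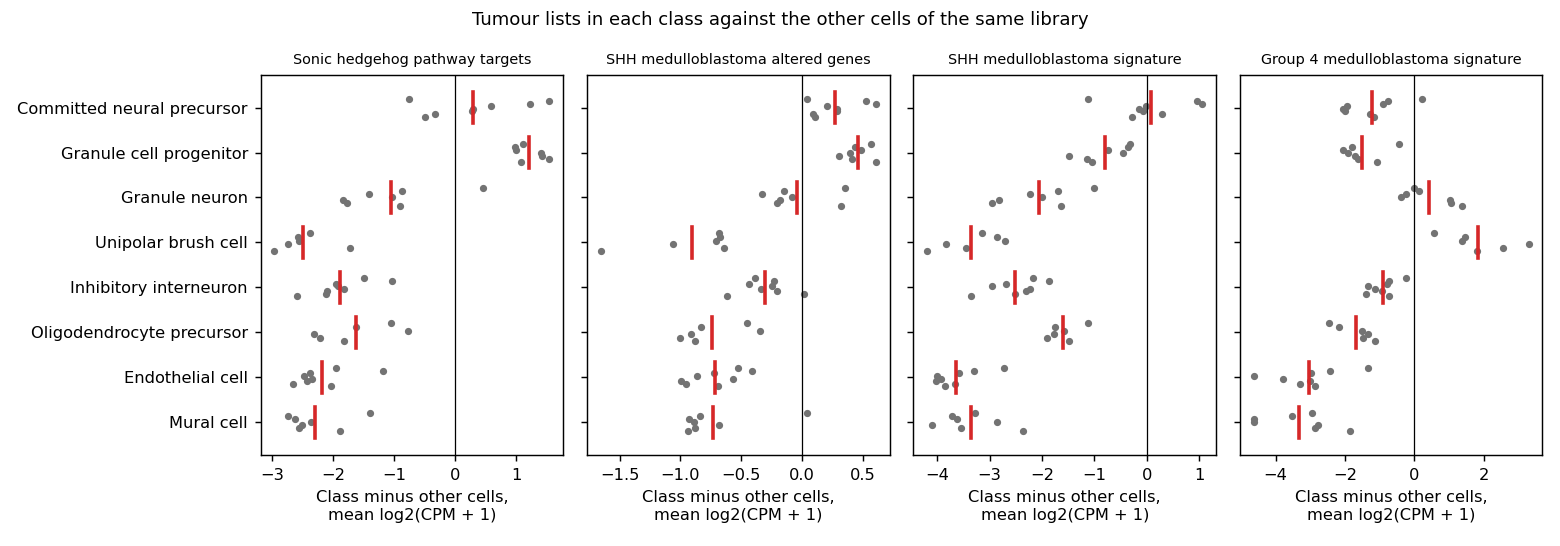
Difference in mean log2(CPM + 1) of 4 lists between a class and all other cells of the same library (x axis), for 8 classes (y axis), with a grey point per library and a red bar at the mean. Sonic hedgehog pathway targets lay above 0 in 7 of 7 libraries of the granule cell progenitor-like class, and Group 4 signature genes in 6 of 6 libraries of the unipolar brush cell-like class.

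In 46 of the 64 pairs the class was lower than the other cells at an adjusted exact p under 0.05. All 8 lists were lower in endothelial-like and in mural-like cells, down to -3.63 for SHH medulloblastoma signature genes in endothelial-like cells (SD 0.44, 0 of 8 libraries higher). SHH signature genes without the marker Atoh1 were lower in granule cell progenitor-like cells by -0.79 (SD 0.45, 0 of 7 libraries higher, adjusted exact p 0.0312), and WNT signature genes by -2.32 (SD 0.38). Against the mean of the other classes at equal weight, 22 pairs were higher and 21 lower, and SHH signature genes in granule cell progenitor-like cells turned to 0.70. With a pseudocount of 10 CPM the latter stood at -0.08 and did not pass, and 8 pairs were higher. With 1 library left out, 29 pairs were lower without E16, P5 or P7 and 30 without E18 or P0.

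By gene, 544 tests of a gene in a class were made, with an adjusted exact p of 0.0434 where every library of 7 or 8 pointed the same way. Hhip stood at 55.0 CPM ± 43.9 (SD, n = 8) in committed precursor-like cells against 2.01 CPM, and Gad1 at 324 CPM ± 136 in inhibitory interneuron-like cells against 12.5 CPM. Dkk2, a Wnt antagonist gene, stood at 40.7 CPM ± 13.7 in mural-like cells against 0.686 CPM. Chd7, a chromatin remodeller altered in medulloblastoma, stood at 568 CPM ± 69.4 in granule neuron-like cells against 222 CPM. Among classes with enough cells in at least 3 libraries, the highest means of other tumour genes were Eomes at 908 CPM ± 265, Mab21l2 at 245 CPM ± 189.5 and Otx2 at 196 CPM ± 124 in unipolar brush cell-like cells. Tnc was highest at 278 CPM ± 73.6 and Wif1 at 134 CPM ± 235 (29.4 CPM without P14, its highest library) in radial glia-like cells, and Pdlim3 at 217 CPM ± 179 (132 CPM without P5) and Ntrk2 at 583 CPM ± 174 in astrocyte-like cells. Fgfr1, altered in pilocytic astrocytoma, was highest in radial glia-like cells at 217 CPM ± 42.8, Sfrp1 in granule cell progenitor-like cells at 242 CPM ± 249.9 (179.5 CPM without P5), and Eya1 in mesenchyme-like cells at 41.5 CPM ± 6.02. Impg2, Nrl, Tert and Gfi1 had class means of at most 2.40 CPM.

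Over stage, the tumour lists did not pass in all cells by the exact permutation test of rho, with adjusted p values of 0.171 for the Group 4 signature (rho 0.617), 0.182 for the SHH signature (0.60), and 0.385 for the Group 3 signature (-0.417). They were 0.420 for Sonic hedgehog targets (0.383), the WNT signature (0.367) and the SHH altered genes (0.367), 0.637 for the pilocytic astrocytoma genes (0.233) and 0.646 for the Group 3 and 4 altered genes (-0.217). Single members passed: Kcna1, a Group 4 gene, rose from 1.66 to 93.0 CPM (slope 0.70, SE 0.07), Hhip from 2.22 to 16.2 CPM (slope 0.39, SE 0.09), and Wif1 from 1.0003 to 62.2 CPM (slope 0.54, SE 0.12). Ntrk2 rose from 14.6 to 164 CPM (slope 0.29, SE 0.07), as did Tcf4 (slope 0.27, SE 0.07), Impg2 (slope 0.53, SE 0.07) and Kmt2c (slope 0.11, SE 0.03). Bcor (slope -0.17, SE 0.04), Ldb1 (slope -0.16, SE 0.03) and Smarca4 (slope -0.13, SE 0.04) fell. Over all genes tested, the rising and falling members numbered 1 and 0 in the WNT, SHH, Group 3 and Group 4 signatures, in the Sonic hedgehog targets and in the pilocytic astrocytoma genes. They were 1 and 2 in the SHH altered genes and 1 and 1 in the Group 3 and 4 altered genes. Adjusted over the list alone they numbered 1 and 1 in the WNT signature, 1 and 2 in the Group 3 signature, 2 and 0 in the Group 4 signature and 0 and 0 in the Group 3 and 4 altered genes. They stayed as over all genes in the other 4 lists.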

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

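The removed barcodes described here lay outside the comparisons, while the Xist and Y-linked counts came from kept cells that entered them. All of the tests in this part were chosen only after the result was seen. The barcodes removed by the filters at P14, 299 in number, held 95.05% of their UMIs in globin genes, and globins were the larger part of the UMIs in 296 of them. The kept cells of that library held 2.01%. Removed barcodes of the other libraries with any held between 50.4% at P5 and 92.0% at E16. The value marks red blood cells or their debris among the deposited barcodes as a group that the filters took out; no test was run on it.

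Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty) were found in 388 kept cells at E10 and 2098 at E12, in libraries that also held Xist, at 762 and 409 CPM. The other libraries held only Xist or only Y-linked transcripts in quantity: Xist stood at 1480 CPM at E14, 1554 CPM at P0 and 1634 CPM at P14, with 0 Y-linked UMIs at E14 and P0 and 1 at P14, while E16, E18, P5 and P7 had 174, 201, 186 and 196 CPM of Y-linked transcripts and 4, 2, 3 and 2 Xist UMIs. If free RNA of another embryo had brought the Y-linked UMIs into the droplets, they should have fallen on cells with and without Xist alike; cells with both were 10.154% of the number that independence gives, 39 against 350 at E10 and 69 against 713 at E12, which argues against that source. The same value of 10.154% is consistent with cells of embryos of both sexes pooled in these libraries. Whether sex took part in any difference between stages stays open, since the sex make-up changed from library to library.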

How the results depend on the processing

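Of these alternatives, a term for period, leaving out E10 and P14 together, radial glia with astrocytes, resolution 2 for trends within classes, and the exclusion of non-neural cells for the lists and the squared term were chosen after seeing the data; the others were planned. No paired analysis was possible because each stage had a single library of its own animals. Unless stated, the cause of a change was not tested; with libraries left out or a period alone, fewer libraries lower what the tests can reach.

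Trend counts over all cells (1605 rising, 1192 falling) fell to 1 and 1 in the embryonic libraries, 16 and 1 in the postnatal ones, and 5 and 1 with a term for period. DESeq2 called 2023 falling genes, and the rank test 589. Leaving out 1 library gave 629 to 2465 rising and 492 to 1964 falling genes. Counts for the squared term went to 1077 and 1467 with DESeq2 and to 39 to 491 positive and 43 to 547 negative genes with 1 library left out. Named genes kept their direction except Cldn11 in the embryonic libraries (-0.24) and Crabp1 (0.0548), Olig3 (0.0968) and Crabp2 (0.31) in the postnatal ones. Of the values for named genes, 415 stayed on their side of the threshold, 71 weakened and 4 reversed; for the squared term 110 stayed and 20 weakened.

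Within classes, leaving out 1 library gave 393 to 802 rising and 460 to 826 falling genes in committed precursor-like cells, 595 to 1031 and 602 to 1026 in granule cell progenitor-like, 295 to 489 and 262 to 553 in granule neuron-like, 137 to 470 and 156 to 511 in inhibitory interneuron-like and 468 to 967 and 293 to 582 in oligodendrocyte precursor-like cells. DESeq2 called 800 and 828 in inhibitory interneuron-like cells. Resolution 2 gave 363 and 436 in committed precursor-like cells, and 17 and 3 in oligodendrocyte precursor-like cells, where it left 4 libraries.

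Class shares gave 0 rising and 0 falling in either period alone, and with 1 library left out 4 to 6 rising and 0 to 3 falling; the share of microglia-like cells turned to -0.30 in the embryonic libraries. Lists over stage gave 0 and 0 in either period alone, 2 to 4 rising and 2 to 3 falling with 1 library left out, and 5 falling without erythroid-like, microglia-like, vascular-like and mesenchyme-like cells; 472 values stayed, 28 weakened and 10 strengthened. Lists within classes gave 9 and 14 with a pseudocount of 10 CPM, 2 rising at resolution 2, and 0 to 5 rising and 0 to 8 falling with 1 library left out.

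Tumour lists gave 8 higher pairs with a pseudocount of 10 CPM, 22 higher and 21 lower with classes at equal weight, and 3 to 5 higher and 29 to 46 lower with 1 library left out, where classes in 6 libraries drop below the number needed. WNT signature genes in inhibitory interneuron-like cells turned to 0.30 with a pseudocount of 10 CPM. With classes at equal weight these pairs turned: WNT signature genes to 0.30 in committed precursor-like, 0.65 in inhibitory interneuron-like and 0.14 in mural-like cells; SHH signature genes to 0.70 in granule cell progenitor-like, 0.0492 in granule neuron-like and 0.51 in oligodendrocyte precursor-like cells; Group 3 signature genes to 0.27 in granule cell progenitor-like and 0.21 in inhibitory interneuron-like cells, and Group 4 genes to 0.0675 and 0.33 there. Sonic hedgehog targets turned to 0.46 in granule neuron-like cells, pilocytic astrocytoma genes to 0.00566 in granule cell progenitor-like cells, and in inhibitory interneuron-like cells SHH altered genes turned to 0.16 and Group 3 and 4 altered genes to 0.0743. Of all values for tumour lists 546 stayed, 47 weakened and 15 reversed. The oligodendrocyte precursor-like class had the fewest libraries, 6, and the smallest library, with 0.158 M UMIs.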

Other observations

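Of the tests in this part, those on the mix of classes, on the order of the libraries and on Mbp were chosen only after the result was seen; the one on a step at birth was planned. Genes rising and falling over stage in all cells could come from a change in the mix of classes alone. Of the called genes that could be tested within a class, 62.673% passed in the same direction within at least 1 class, 1271 of 2028, and 73 (3.60%) passed in the opposite direction. Calls within classes that were independent of the direction in all cells would give 24.7% in either direction. For the genes tested, the values argue against the mix of classes as the whole cause. Of the 2797 called genes only 2028 could be tested within a class, and for the others the question stays open. Sums over a class are also part of the sums over all cells and share their libraries, so these calls are not independent measurements. The bound for this test, 2 times the share under independence, was set with both shares in view and replaced an earlier one of 30%. Shifts between finer cell states stay open, since classes changed clusters with stage, and so does free RNA of other classes, which was not tested here. A step between embryonic and postnatal libraries, which lie on different rows of index plates, is not excluded: of genes with an unadjusted p under 0.05 over the embryonic libraries, 59.473% had the same sign over the postnatal ones, just under the bound of 60% set for excluding it, against 53.2% of all genes and 45.1% when the periods changed roles. Stage, birth and batch therefore cannot be told apart for these genes. A chance order of the libraries is unlikely as the source of the number of calls. The real order gave 2797 and the highest of 99 other orders 109, so that 1 of 100 orders, the real one, reached the real count. With 100 orders the test can reach no smaller share. Random orders also mix embryonic with postnatal libraries, so the test does not bear on a step between them.

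Mbp rose in granule neuron-like cells, which do not make myelin, though the myelin list as a whole did not pass there (rho 0.643, adjusted exact p 0.259). Free RNA spread evenly over droplets should give each cell its share by depth, yet at P14 the 5% of granule neuron-like cells richest in Mbp held 75.7% of its UMIs against 10.8% in a Poisson draw, 6.9931 times as much, which argues against an even spread. Oligodendrocytes captured with granule neurons should bring Mbp and other myelin transcripts in their own ratio. The ratio of Mbp to the sum of Mag, Mog, Mobp and Cldn11 was 8.69 in granule neuron-like and 0.587 in oligodendrocyte-like cells, 14.807 times apart, and 1.88 in oligodendrocyte precursor-like cells, which argues against such captures as the main source. Mbp was not limited to neurons. At P14 it stood at 1830.4 CPM in granule neuron-like cells and at 2381 CPM in inhibitory interneuron-like cells, but also at 940.2 CPM in mural-like, 793 CPM in astrocyte-like, 654 CPM in radial glia-like and 585 CPM in erythroid-like cells. The ratio to the other myelin transcripts was raised there too, at 7.85, 5.52, 8.61 and 6.02, so transcription in neurons cannot be the source in these classes. Endothelial-like cells had less Mbp, 273 CPM, with a ratio of 5.12. Mesenchyme-like cells had 676 CPM and a ratio of 0.838, but at P7 their ratio was 0.247 against 1.16 in oligodendrocyte-like cells, with 7.35 UMIs of the other myelin genes per cell and 1.81 of Mbp. Their ratio therefore does not inform on the source of Mbp. A source shared by several classes, such as fragments of myelinating processes, which may carry Mbp transcripts without the others, stays open. Depth differed between classes, so CPM and UMIs per cell gave different gaps. Mbp UMIs per cell at P14 were 6.37 in granule neuron-like and 7.44 in inhibitory interneuron-like cells. They were 5.57 in ependymal-like, 4.97 in unipolar brush cell-like, 4.41 in astrocyte-like, 4.10 in mural-like and 2.99 in endothelial-like cells. Whether all classes share a background was not tested, so transcription of Mbp in neurons stays open. A source in another cell state was not tested either. The rise of Mndal in committed precursor-like, granule cell progenitor-like and granule neuron-like cells was not tested further.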
